A study of Sus scrofa with 32 samples.

How the data were processed

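Fetal liver RNA of Pietrain pigs was measured on 32 porcine expression arrays, 1 per sample, from offspring of gilts fed a control or a methyl-enriched gestation diet and collected at 35, 63 or 91 dpc. Per the labels' protocols, RNA was isolated with TRI Reagent, treated with DNase and cleaned on RNeasy columns, and biotinylated cRNA was made from 0.5 ug total RNA. GCOS 1.1.1 is named per the submitters' processing notes, without its role. The deposited values are on a log2 scale, 1 per probe set and array, from 2.20 to 16.6, with 26.1% of the values within 0.01 of the lowest one. The array medians ran from 3.84 to 4.23 and the sorted values of each array lay at most 0.39 from their average over the arrays. The arrays therefore appear to have been made comparable before deposit, but no method is given in the sources used here. The values were therefore used as deposited, with no further log transform and no further normalization. Array images were not used here.

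The table had 24123 probe sets, of which 124 control probe sets were set aside. Of the other 23999, 15327 were kept because their value lay above the array's 40th percentile (2.74 to 2.93) in at least 5 arrays. Gene symbols came from the array annotation: 10099 probe sets had 1 symbol, 198 had several and 13826 had none. Among those kept, 7625 had 1 symbol, for 5594 genes. Probe sets with no symbol or several are counted in totals but were not placed in gene lists. Many IDs ending in _s_at or _x_at may match several transcripts.

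limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8) fitted a mean for each of the 6 groups of age and diet, with moderated standard errors that follow an intensity trend, 26 residual degrees of freedom and a median prior of 4.14 degrees of freedom. The contrasts were methyl minus control diet at each age, the average of these, the F test of their differences between ages, and the change between successive ages averaged over diets. Calls are at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets of a contrast. Replicate numbers follow the order of the deposited samples and only name them, so they pair nothing, and no paired test was made. The labels give neither dam, litter, fetal sex nor array batch.

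Of 35 gene lists fixed for liver functions, one-carbon metabolism, methylation, blood and immune cells, neighbouring tissues, stress and growth, 34 had at least 5 measured genes and were tested, each gene by its brightest probe set. The list of adrenal, gonad and kidney markers had 3 measured genes and was not tested. camera was run with a correlation of 0.01 and again with the estimated correlation, and fry was run on the same lists, all adjusted over the 34 lists. Diet differences of list means were also tested by exact two-sided permutation of the arrays of an age (252 or 924 arrangements). The developmental position of an array is its mean over the 200 probe sets with the strongest rise between 2 ages minus that over the 200 with the strongest fall, each centred on its mean over all arrays. These probe sets were chosen on the same arrays, averaged over diets.

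The genes named in the text followed a rule. For each contrast it takes up to 10 named genes higher and 10 lower with the largest differences among those called, and the 10 with the smallest p where fewer than 10 pass. It adds 5 for the averaged effect and 5 for the interaction, up to 4 members of each list by p, and 14 genes looked at whatever their p. Of these, CBS is not named on the array, and 1 gene is not reported here. For the other genes of that group that the comparisons do not describe, no diet effect was called. The contrasts, lists, naming rule and most alternatives were chosen before the data were examined.

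Alternatives were no intensity trend, robust spread, no filter, a stricter filter at the 60th percentile, quantile normalization, array weights, 1 probe set per gene, arrays of the compared ages alone, a threshold of 0.10, and covariates for the Y-linked gene EIF1AY, the 3' to 5' ratio and the mean erythroid level. Each array was also left out in turn. After the data had been seen, a gap between the spike-in probe sets bioC and bioB was found to part the arrays at 1.2, and the batch was then tried as a block, with each batch alone and together with array weights. The second principal component of the arrays (5.98% of the variance, after 69.4% for the first) ran from -35.3 to -1.26 in high-gap and from 7.28 to 35.2 in low-gap arrays. The mean 3' to 5' ratio was 1.90 ± 0.28 (SD) in 18 high-gap and 1.40 ± 0.17 in 14 low-gap arrays, and 3691 probe sets differed between batches by limma. The fit without the 3 arrays with little EIF1AY signal was also added then. The fit and the list test were tested on simulated data with planted changes, in which each probe set or gene varied independently of the others. For the fit, 67, 67 and 66 changes of log2 size 0.5, 1 and 2 were planted together in a contrast. The noise was normal, with no lower limit on the signal. Many calls at once make the adjusted threshold easier to pass, so the shares called do not carry over to a few changes. Other splits of the arrays (100 per result, seed 20240) gave the counts that regrouped samples give.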

Results

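Liver RNA from 32 Pietrain pig fetuses was measured on a porcine expression array at 3 gestational ages, 35, 63 and 91 days post coitum (dpc). The mothers (gilts) had received either a control gestation diet or a diet enriched in methylating micronutrients, nutrients that feed the supply of methyl groups. There were 5 control and 5 methyl-diet arrays at 35 dpc, 6 and 6 at 63 dpc, and 5 and 5 at 91 dpc. The number of arrays limits the precision. The labels tie no array to a dam, and fetuses of one dam in one group would make every p-value below too small. The deposited values are log2 signals whose array medians ran from 3.84 to 4.23, and which scaling or normalization between arrays produced them is unknown. The spike-in control probe sets sorted the arrays into 18 with a large gap between bioC and bioB (1.60 to 2.26) and 14 with a small gap (0.45 to 0.83), called the high-gap and low-gap batches here. Each diet had 3 high-gap and 2 low-gap arrays at 35 and at 91 dpc, and 3 and 3 at 63 dpc. This split was found after the data were seen, so blocked values (batch as a term in the fit) and within-batch values stand beside the results. As diets were balanced over the batches at each age, the block cannot change a diet difference, only its standard error. Signs within batches come from the same arrays that gave the calls, so they are no independent check. Of 15327 probe sets tested, 7625 carried a single gene symbol, for 5594 genes.

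The comparison of 63 with 35 dpc asked how the fetal liver changed in mid gestation. KLKB1, the precursor of plasma kallikrein, went from 5.12 ± 0.96 (SD, n = 10) to 9.15 ± 0.31 (n = 12), a 16.4-fold rise (log2 difference 4.03 ± 0.24 SE, limma adjusted p = 3.85e-13). ALB, serum albumin, rose from 11.4 ± 0.71 to 14.8 ± 0.34 (3.37 ± 0.19, limma adjusted p = 7.79e-14), and IGFBP2, an insulin-like growth factor binding protein, rose 15.6-fold (3.96 ± 0.37). ABCB11, the bile salt export pump, rose by 2.83 ± 0.20, and the fructose transporter SLC2A5 by 2.85 ± 0.54. The other genes with the largest rises were LRRN3 (3.65), PDZK1 (3.41), PALMD (3.17), VSNL1 (3.14) and IFIT1 (3.06). In the other direction, HPD, a tyrosine breakdown enzyme, went from 11.2 ± 0.60 to 4.83 ± 2.13 (log2 difference -6.41 ± 0.56, at least 85.1-fold lower, limma adjusted p = 1.73e-10). TRH, which encodes thyrotropin-releasing hormone, fell by 4.12 ± 0.28 to a mean of 2.78. For TRH, and for HPD in some arrays, the signal at 63 dpc was near background (the arrays' 40th percentiles were 2.74 to 2.93), so both falls are lower bounds. The transcriptional regulator CITED1 fell by 3.91 ± 0.26 and the plasma glutathione peroxidase GPX3 fell by 3.36 ± 0.31. EPO, which encodes erythropoietin, fell by 2.66 ± 0.28, and FGF12, CAPNS1, NANOS1, SELENOM and AQP3 had log2 differences from -3.46 to -2.99. VSNL1 in most arrays at 35 dpc, IFIT1 and SLC2A5 in single arrays at 35 dpc, and FGF12 and NANOS1 in 1 or 2 arrays at 63 dpc were near background as well, so these differences are lower bounds in size. limma called 9278 of 15327 probe sets, 4985 higher and 4293 lower, and with the batch as a block 9827, 5238 higher and 4589 lower. The balance turned to 4309 higher and 5198 lower after quantile normalization, and to 1739 and 2195 with 1 probe set per gene.

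Of the 34 gene lists tested between 35 and 63 dpc, camera, which compares a list with all other genes, called 5 higher and 3 lower. Of 36 measured hepatocyte secreted proteins 24 rose, 4 fell and the others did not pass, with ITIH3 up by 2.25 ± 0.15 and F5, coagulation factor V, up by 2.12 ± 0.15 (camera adjusted p = 1.52e-05; adjusted p = 0.475 with an estimated correlation). Complement and acute phase genes had 13 rises and 5 falls among 23, with C1S up by 2.07 ± 0.14 (camera adjusted p = 0.0189; adjusted p = 0.475 with an estimated correlation). Neutrophil and granulocyte genes had 8 rises and 0 falls among 10, with lactoferrin (LTF) up by 1.15 ± 0.17 (camera adjusted p = 0.0169; adjusted p = 0.475 with an estimated correlation). Cholesterol synthesis had 8 rises and 2 falls among 14, with SQLE up by 1.27 ± 0.14 (camera adjusted p = 0.0169; adjusted p = 0.475 with an estimated correlation). Bile acid synthesis and transport had 6 rises and 1 fall among 9, with the bile acid uptake carrier SLC10A1 up by 1.85 ± 0.22 (camera adjusted p = 0.0175; adjusted p = 0.428 with an estimated correlation). Oxidative phosphorylation genes fell, 35 of 51 against 3 that rose, with COX7A2 down (log2 difference -0.83 ± 0.07) and NDUFA9 down (-0.95 ± 0.10; camera adjusted p = 7.89e-05; adjusted p = 0.475 with an estimated correlation). Antioxidant genes had 21 falls and 4 rises among 29, with heme oxygenase HMOX1 at -1.22 ± 0.11 (camera adjusted p = 0.0138; adjusted p = 0.475 with an estimated correlation). Cell cycle and DNA replication genes had 21 falls and 5 rises among 35, with RRM2 at -1.63 ± 0.18 and PLK1 at -1.30 ± 0.13 (camera adjusted p = 0.0175; adjusted p = 0.523 with an estimated correlation). Adjusted over the list alone the counts were the same, except for 9 rises in cholesterol synthesis and 22 falls among antioxidant genes. All 8 calls were kept with the batch as a block, each list mean had the same sign in both batches (0.67 and 0.54 for hepatocyte secreted proteins), and 6 of the 8 were kept with the mean erythroid level as a covariate. The calls lost with it were cell cycle (adjusted p = 0.383) and bile acid genes (adjusted p = 0.0691), and the antioxidant call was lost with the mean of all probe sets of a gene (camera adjusted p = 0.0668). The estimated correlation left 0 lists called and fry called 26 of 34. fry's directional p asks whether the genes of a list move on balance one way and its mixed p whether they change in either direction, and neither compares the list with other genes.

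The comparison of 91 with 63 dpc asked how the liver changed in late gestation. GSTA1, a glutathione transferase, went from 3.46 ± 0.93 (SD, n = 12) to 8.95 ± 2.11 (n = 10), a log2 rise of 5.48 ± 0.54 (at least 44.7-fold, limma adjusted p = 9.24e-10). KLF9, a transcription factor induced by glucocorticoids, rose from 2.45 ± 0.13 to 7.13 ± 0.57 (4.68 ± 0.13, at least 25.7-fold, limma adjusted p = 5.86e-22). CA3, a carbonic anhydrase, rose by 3.10 ± 0.15, and TNNI2 (3.29), CYP2C91 (3.24), LRRN3 (3.07), NFIB (3.05), APCS (2.92), LEAP2 (2.92) and STEAP4 (2.88) rose too. At 63 dpc KLF9, CYP2C91 and CA3 (mean 2.33) were near background, as was GSTA1 in some arrays, so these rises are lower bounds. Embryonic globin HBE1 went the other way, from 7.70 ± 0.47 to 3.62 ± 0.58 (log2 difference -4.08 ± 0.21, 16.9-fold lower, limma adjusted p = 2.63e-15). The glucose transporter SLC2A1 fell by 3.84 ± 0.20 and BCL11A, a repressor of fetal globin genes, fell by 2.76 ± 0.16. PLA2G1B, AQP3, TNNI1, CDA, EPDR1, MBOAT1 and FIBIN had log2 differences between -3.14 and -2.49, that of AQP3 being a lower bound in size because some arrays at 91 dpc were near background. limma called 8963 probe sets, 4523 higher and 4440 lower, and with the batch as a block 9351, 4669 higher and 4682 lower. Quantile normalization gave 4207 higher and 5126 lower, and 1 probe set per gene 1281 and 2264. The mean of the erythroid list fell from 10.7 to 9.02 over the same interval. With that mean as a covariate, 808 probe sets were called, and the GSTA1 and APCS differences became -0.96 and -0.61.

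camera called 8 lists higher and 6 lower between 63 and 91 dpc. Erythroid genes fell, 14 of 16 against 1 that rose, with the erythropoietin receptor EPOR at -2.38 ± 0.14 (camera adjusted p = 2.13e-06; adjusted p = 0.230 with an estimated correlation). Cell cycle and DNA replication genes had 28 falls and 0 rises among 35, with AURKA at -1.82 ± 0.12 and MCM2 at -1.86 ± 0.13 (camera adjusted p = 3.48e-08; adjusted p = 0.149 with an estimated correlation). Stem, progenitor and megakaryocytic markers had 7 falls and 1 rise among 8, with ITGA2B, the platelet integrin, at -1.88 ± 0.15 (camera adjusted p = 0.0219; adjusted p = 0.257 with an estimated correlation). Neutrophil and granulocyte genes had 8 falls and 1 rise among 10, with ELANE at -2.15 ± 0.16 and PRTN3 at -2.14 ± 0.19 (camera adjusted p = 0.0370; adjusted p = 0.484 with an estimated correlation; 0.0614 without control 63 dpc replicate 5). Oxidative phosphorylation had 35 falls and 1 rise among 51, with NDUFA1 at -1.05 ± 0.07 (camera adjusted p = 0.000622; adjusted p = 0.478 with an estimated correlation). Antioxidant genes had 19 falls and 2 rises among 29, with PRDX2 at -1.48 ± 0.12 (camera adjusted p = 0.00376; adjusted p = 0.306 with an estimated correlation). The mean erythroid level fell over the same interval. With it as a covariate camera kept the calls of oxidative phosphorylation (adjusted p = 0.0426) and antioxidant genes (adjusted p = 0.0359), although the PRDX2 difference became 0.034. The cell cycle (adjusted p = 0.709), stem and progenitor (0.493) and neutrophil (0.615) calls were lost, the neutrophil list with the direction turned to up. The erythroid call was lost too (camera adjusted p = 0.602, direction up). Because the covariate is the mean of that same list, this loss was fixed in advance and tests nothing.

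The 8 lists called higher between 63 and 91 dpc included markers of immune cells and groups of liver functions. Lymphocyte and antigen presentation genes had 7 rises and 0 falls among 9, with the class II genes SLA-DRA up by 2.19 ± 0.27 and SLA-DQA1 by 1.91 ± 0.18 (camera adjusted p = 0.000249; adjusted p = 0.149 with an estimated correlation). Macrophage and Kupffer cell markers had 8 rises and 3 falls among 16, with CD5L up by 2.13 ± 0.16, CD163 by 1.63 ± 0.12 and MRC1 by 1.96 ± 0.17 (camera adjusted p = 0.00687; adjusted p = 0.354 with an estimated correlation). Complement and acute phase genes had 13 rises and 3 falls among 23, with C8B up by 2.42 ± 0.13 (camera adjusted p = 0.000384; adjusted p = 0.149 with an estimated correlation). Hepatocyte secreted proteins had 18 rises and 7 falls among 36, with coagulation factor IX (F9) up by 1.51 ± 0.12 (camera adjusted p = 0.00360; adjusted p = 0.484 with an estimated correlation). Cholesterol synthesis had 9 rises and 0 falls among 14 (camera adjusted p = 0.000384; adjusted p = 0.149 with an estimated correlation). Bile acid genes had 6 rises and 1 fall among 9, with ABCB11 up by 2.46 ± 0.20 (camera adjusted p = 0.0106; adjusted p = 0.149 with an estimated correlation). Glucocorticoid response and clock genes had 7 rises and 1 fall among 13, with SGK1 up by 0.83 ± 0.11 (camera adjusted p = 0.00655; adjusted p = 0.149 with an estimated correlation). Xenobiotic metabolism had 12 rises and 5 falls among 27, with the sulfotransferase SULT2A1 up by 2.63 ± 0.14, a lower bound from background at 63 dpc (camera adjusted p = 0.0124; adjusted p = 0.301 with an estimated correlation). Adjusted over the list alone the counts of the 14 lists were the same, except for 15 falls in the erythroid, 29 in the cell cycle and 36 in the oxidative phosphorylation list and 19 rises in hepatocyte secreted proteins. All 14 calls of this interval were kept with the batch as a block, each list mean had the same sign in both batches (-1.57 and -1.75 for erythroid genes), and 7 were kept with the erythroid mean as a covariate. Of the lists called higher it ended the calls of glucocorticoid response (camera adjusted p = 0.249), bile acid (0.636) and xenobiotic genes (0.602), and the neutrophil call was also lost without the filter (0.0660). The estimated correlation left 0 and fry called 27 of 34.

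Single genes of methyl group metabolism and DNA methylation changed with age, although neither list was called. BHMT, which remethylates homocysteine from betaine, rose by 1.59 ± 0.22 from 35 to 63 dpc (limma adjusted p = 3.72e-07). GNMT, the enzyme that uses up surplus S-adenosylmethionine, fell by 0.74 ± 0.15 over the same interval, to levels close to background. Its mean went from 3.54 to 3.17 in controls and from 4.35 to 3.23 under the methyl diet. MAT1A, which makes S-adenosylmethionine in liver, fell by 0.42 ± 0.08 from 63 to 91 dpc. DNMT3B, a de novo DNA methyltransferase, fell by 1.25 ± 0.23 and then by 0.65 ± 0.23. Its means at 91 dpc were near background (2.88 in controls and 3.11 under the methyl diet). DNMT1, the maintenance methyltransferase, rose by 0.28 and then fell by 0.69 ± 0.12, and DNMT3A rose by 0.49 in the first interval. The methionine cycle list had 7 rises and 2 falls among 13 in the first interval (camera adjusted p = 0.166) and 2 rises and 4 falls in the second (camera adjusted p = 0.853). The DNA methylation list had 3 rises and 4 falls among 10 (camera adjusted p = 0.925), then 1 rise and 4 falls (camera adjusted p = 0.576). Adult beta globin HBB rose by 1.34 ± 0.24 and 0.68 ± 0.24, and IGFBP1 by 1.13 ± 0.18 and 0.79 ± 0.18. A second, dimmer IGFBP1 probe set fell by 0.39 in the first interval. The brightest IGF2 probe set passed in neither interval (-0.05 and 0.11), whereas 1 of the 8 other IGF2 probe sets fell by 1.14 in the second. With the erythroid mean as a covariate, the second-interval differences of DNMT3B (0.64) and IGFBP1 (-0.052) took the opposite sign.

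**Figure D1:**
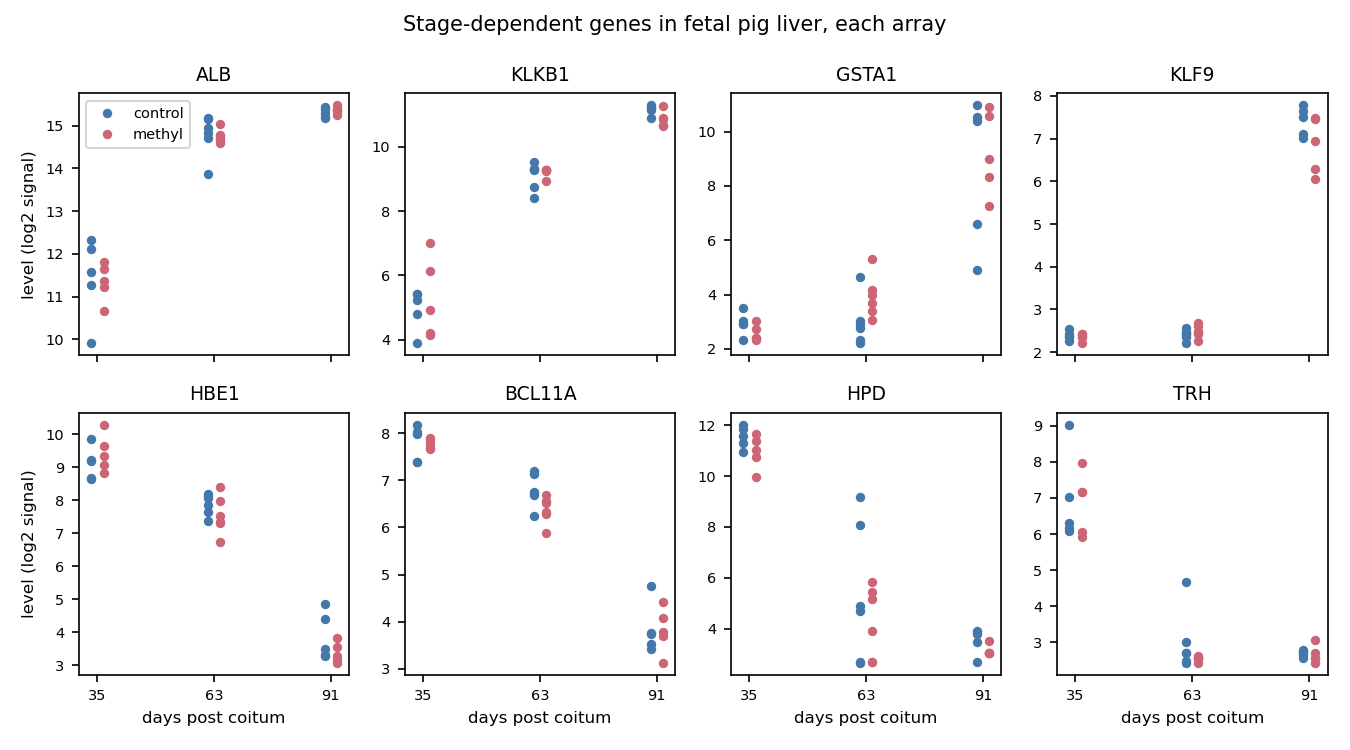
Log2 signal of ALB, KLKB1, GSTA1, KLF9, HBE1, BCL11A, HPD and TRH in each of the 32 arrays, by gestational age (dpc) and diet, 1 point per array. ALB and KLKB1 rose from 35 to 63 dpc while HPD and TRH fell, and GSTA1 and KLF9 rose from 63 to 91 dpc while HBE1 and BCL11A fell.

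The diet comparison at 35 dpc asked whether the maternal diet changed the early fetal liver. A probe set shared by CYP4A21 and CYP4A24, fatty acid and bile acid hydroxylases of the pig, was higher in the methyl-diet fetuses: 6.48 ± 0.51 against 5.00 ± 0.47 (SD, n = 5 each; log2 difference 1.47 ± 0.28 SE, limma adjusted p = 0.0381), with every methyl-diet array above every control array. Its ID ends in _s_at, so it may match several transcripts. The difference was 1.79 within the high-gap batch and 0.998 within the low-gap batch, and the blocked adjusted p by limma was 0.0351. A second probe set with the same symbols read 6.91 ± 0.87 against 4.58 ± 1.53 (2.33 ± 0.53, limma adjusted p = 0.130, blocked 0.0338; 2.98 and 1.36 within batches). The first call was lost on leaving out any of 13 arrays, among them 7 at 35 dpc, and its difference then ran from 1.32 without control 35 dpc replicate 1 to 1.66 without methyl 35 dpc replicate 1. limma called 6 probe sets, 3 higher and 3 lower, of which 5 have no gene name, against 933 at an unadjusted p under 0.05 where chance gives 766. All 6 were also among the 7 called with the batch as a block, with the same sign in both batches. With fewer arrays, the high-gap batch alone kept 2 of the 6 calls and the low-gap batch alone 0. Of the 6, 5 stayed under a mean of 4 in both groups. Without control 35 dpc replicate 4 the count was 13, and it was 0 with the arrays of this stage alone.

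Among named genes that did not pass at 35 dpc, VSIG2 had a log2 difference of -0.81 ± 0.17 (limma adjusted p = 0.0913), MICALL2 0.92 ± 0.20 (limma adjusted p = 0.0991) and GATAD2A 0.75 ± 0.16, with 0.16 and 0.29 in 2 brighter GATAD2A probe sets. XIRP1 (1.32), WDR91 (0.85, against 0.07 and -0.22 in its other probe sets), MAP2K6 (0.67), CDHR4 (0.62) and TMEM87B (0.52) were on the higher side, and KLRK1 (-1.01) and MRPS35 (-0.99) on the lower. For VSIG2, GATAD2A and WDR91 the lower group was near background, so the size of these uncalled differences is uncertain. GNMT read 4.35 ± 0.37 against 3.54 ± 0.29 (0.81 ± 0.23, limma adjusted p = 0.427). The methionine cycle list of 13 genes had 0 calls over all probe sets, and 2 higher (GNMT and the choline oxidizing enzyme CHDH, 0.82 ± 0.26) and 1 lower (CTH, -0.49 ± 0.17) adjusted over the list alone, with camera adjusted p = 0.349. camera called 2 lists lower. Of 24 hypoxia, heat shock and unfolded protein response genes, 17 had negative differences, 0 passed over all probe sets and 3 were lower adjusted over the list alone: the chaperones HSPA8 (-0.44 ± 0.14) and HSPE1 (-0.30 ± 0.09), and asparagine synthetase ASNS (-0.35 ± 0.11). The camera adjusted p was 0.0137 for a mean of -0.18 (blocked 0.0176; -0.23 and -0.10 within batches; 0.0733 with the mean of all probe sets of a gene; adjusted p = 0.83 with an estimated correlation; 0.0634 without control 35 dpc replicate 2). Of 58 ribosomal protein genes 45 had negative differences and 0 passed over all probe sets or adjusted over the list alone, RPS24 standing at -0.22 and RPL9 at -0.20, with a list mean of -0.06 (camera adjusted p = 0.0137, blocked 0.0112; adjusted p = 0.83 with an estimated correlation). Their mean was -0.09 within the high-gap batch and 0.0012 within the low-gap batch, with adjusted p = 0.968 by camera without methyl 35 dpc replicate 5 and 0.523 after quantile normalization. fry called 0 of the 34 lists, and an exact permutation test of the list means gave no p under 0.103. Planted changes were called by limma at this stage in 10.4% of cases for a log2 size of 0.5, 64.2% for 1 and 97.0% for 2, with 4 false calls. These shares hold for many changes planted at once and are likely too high for a few.

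At 63 dpc the same question was put to 6 control and 6 methyl-diet arrays: limma called 0 probe sets, with 219 at an unadjusted p under 0.05 where chance gives 766, and its smallest adjusted p was 0.75. The count was also 0 without an intensity trend, with robust spread, without the filter, with array weights or with the batch as a block, and 4 with block and weights together. Of 13 methionine cycle genes 11 had positive differences, 0 passed over all probe sets or adjusted over the list alone, and the list mean was 9.26 ± 0.12 against 9.10 ± 0.13 (SD, n = 6 each). AHCY, which breaks down S-adenosylhomocysteine, differed by 0.38 ± 0.15, MAT1A by 0.26 ± 0.10 and BHMT by 0.36 ± 0.29. camera called the list higher (mean 0.16, adjusted p = 0.00611, blocked 0.00184; 0.18 and 0.15 within batches; adjusted p = 0.170 with an estimated correlation; 0.0611 without control 63 dpc replicate 6). The exact permutation p of its mean was 0.0411, adjusted 0.294. All 10 neutrophil and granulocyte genes had positive differences, 0 passed either way, and the list mean was 8.86 ± 0.29 against 8.46 ± 0.17. The calgranulins S100A12 and S100A8 differed by 0.86 ± 0.34 and 0.73 ± 0.34, and LTF by 0.57 ± 0.24. camera called this list higher (mean 0.40, adjusted p = 2.22e-06, blocked 7.88e-06; 0.53 and 0.27 within batches; adjusted p = 0.170 with an estimated correlation), and the exact permutation p was 0.0152, adjusted 0.258. Urea cycle and amino acid breakdown genes had positive differences in 17 of 22, 0 passed either way, with GOT2 at 0.30 ± 0.10 and tyrosine aminotransferase TAT at 0.67 ± 0.21 (0.84 in its other probe set). camera called them higher (mean 0.09, adjusted p = 0.00390, blocked 0.00184; 0.06 and 0.13 within batches; adjusted p = 0.255 with an estimated correlation; 0.0640 without control 63 dpc replicate 5). The number of lists called was 7 without control 63 dpc replicate 4 or methyl 63 dpc replicate 6, 6 without methyl 63 dpc replicate 2 or 4, and 1 without control 63 dpc replicate 6.

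The named genes with the smallest p at 63 dpc, each with a limma adjusted p of 1, included PPARGC1A, a coactivator of gluconeogenic genes (0.90 ± 0.23), and AOAH, an enzyme that detoxifies endotoxin (0.71 ± 0.17). EGR1, an immediate early transcription factor, stood at 1.15 ± 0.31 in a probe set whose ID ends in _s_at and at 1.44 and 0.28 in its others. FST, the activin binding protein follistatin, stood at -0.61 ± 0.18 (-0.33 in its other probe set) and SELENOM at -1.09 ± 0.33. HK3 (0.49), TRAM1 (0.59), ADD3 (0.79, and 0.87 in its other probe set) and NANOS1 (-0.93) completed the group with TAT. The other TRAM1 probe sets, all brighter, stood at 0.11, 0.20 and 0.11. The camera adjusted p was 0.157 for the folate cycle, 0.977 for B vitamin, choline and zinc handling, 0.766 for DNA methylation, 0.921 for histone methylation and 0.921 for imprinted genes. fry and the exact permutation test of list means each called 0 of the 34 lists. The smallest exact permutation p at this age was 0.00866 (adjusted 0.258), in neither the methionine cycle nor the neutrophil list. Before adjustment 5 lists were under 0.05. Planted changes were called by limma at this stage in 17.9% of cases for a log2 size of 0.5, 76.1% for 1 and 97.0% for 2, with 10 false calls. Many changes were planted at once, so for a few real changes these shares are likely too high. A planted shift of 0.3 was called by camera in 3 of 3 lists, with 0 of the 31 others. The simulated genes varied independently, so this says nothing about false calls from correlated genes. Of the 100 splits of the real arrays at this age, 53 other than the real one called a list.

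The diet comparison at 91 dpc asked the question for the late fetal liver, and limma called 11 probe sets, 5 higher and 6 lower, 5 of them with a gene name. CA3, a carbonic anhydrase of muscle and liver, was higher in the methyl-diet fetuses, 6.04 ± 0.51 against 4.81 ± 0.67 (SD, n = 5 each; 2.34-fold, log2 standard error 0.23, limma adjusted p = 0.0206), with every methyl-diet array above every control array. Its other probe set read 6.86 against 6.07 (0.78 ± 0.27, limma adjusted p = 0.457). DDX39B, an RNA helicase of mRNA splicing and export, was lower in 1 of its 2 probe sets, 3.36 ± 0.57 against 6.70 ± 0.87 (-3.35 ± 0.60, at least 10.2-fold, limma adjusted p = 0.0206), with no overlap of the groups. The brighter DDX39B probe set read 10.01 in both diets (0.0022 ± 0.14, limma adjusted p = 1). SATB1, a chromatin organizer, was lower in 1 of its 3 probe sets (2.23 ± 0.05 against 3.20 ± 0.47, -0.97 ± 0.15, limma adjusted p = 0.00471), again without overlap, but 4 of 5 methyl-diet arrays stood at the lowest value in the data. Its other probe sets stood at -0.63 and -0.33, with limma adjusted p values of 0.476 and 1. The probe set at -0.33 was by far the brightest, at 7.95 ± 0.54 against 8.28 ± 0.55, and was not called. LRP6, a Wnt co-receptor, was lower (2.88 ± 0.26 against 4.04 ± 0.78, -1.15 ± 0.23, limma adjusted p = 0.0336), its other probe set standing at -0.49 ± 0.29. SPARCL1, a matrix protein, was lower as well (2.62 ± 0.28 against 3.52 ± 0.70, -0.90 ± 0.18, limma adjusted p = 0.0424), and the groups overlapped for both genes. The methyl-diet means of SATB1, LRP6 and SPARCL1 were near background, as was DDX39B in some methyl-diet arrays, so these differences are lower bounds in size. Averaged over the arrays of all ages, SATB1 (2.39), SPARCL1 (2.52) and LRP6 (2.86) were near background too, and CA3 was so at 63 dpc (SD 0.12). The fit pools the spread over all ages, so the standard errors of these genes at 91 dpc may be too small. Within the high-gap and low-gap batches the differences were 1.14 and 1.35 for CA3, -3.89 and -2.54 for DDX39B, and -0.81 and -1.22 for SATB1. They were -1.12 and -1.20 for LRP6 and -1.27 and -0.35 for SPARCL1. The blocked adjusted p by limma was 0.0163 for CA3, 0.0107 for DDX39B, 0.00637 for SATB1, 0.0163 for LRP6 and 0.0272 for SPARCL1.

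**Figure D2:**
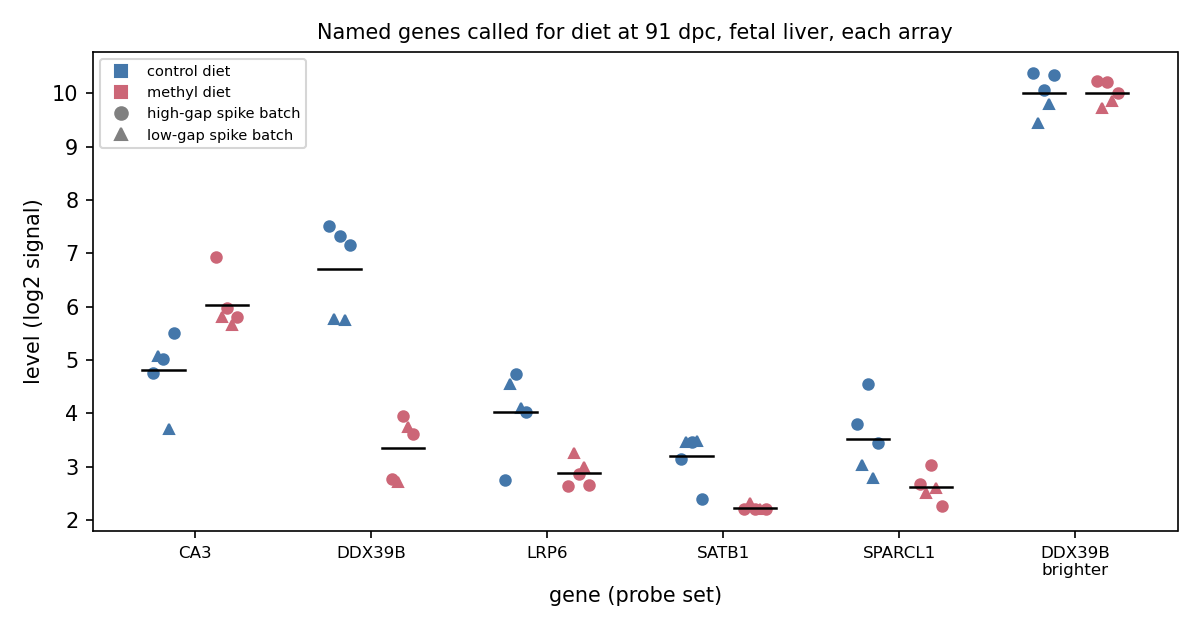
Log2 signal at 91 dpc of CA3, DDX39B, LRP6, SATB1 and SPARCL1, and of the brighter DDX39B probe set, in 5 control and 5 methyl-diet arrays, with group means as horizontal bars, circles for the high-gap and triangles for the low-gap spike batch. The called probe sets stood higher for CA3 and lower for the other 4 genes under the methyl diet, while the brighter DDX39B probe set averaged 10.01 in both diets.

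All 11 probe sets at 91 dpc were among the 15 called with the batch as a block, with the same sign in both batches. The block left the differences themselves unchanged, since diets were balanced over the batches. With fewer arrays, the high-gap batch alone kept 4 of the 11 calls and the low-gap batch alone 1. At 91 dpc 1000 probe sets had an unadjusted p under 0.05 where chance gives 766. After quantile normalization 9 were called, 5 higher and 4 lower. The count rested on single arrays: it was 1 without methyl 91 dpc replicate 1, 7 without methyl 91 dpc replicate 5, 20 without control 91 dpc replicate 1 or methyl 91 dpc replicate 4, 32 without control 91 dpc replicate 4 and 43 without methyl 91 dpc replicate 2. The CA3 and DDX39B calls were lost without methyl 91 dpc replicate 1, and SPARCL1 was lost on leaving out any of 28 of the 32 arrays. The LRP6 call was lost without control 91 dpc replicate 2, 3 or 5 or methyl 91 dpc replicate 1, 3 or 5, whereas SATB1 was kept without each of the 32. The count was 0 with the arrays of this stage alone and 1 without the 3 arrays with little EIF1AY signal, a Y-linked gene, and none of the 11 was called then. Those arrays were methyl 91 dpc replicates 4 and 5 and control 63 dpc replicate 2. At 91 dpc low EIF1AY thus lay in the methyl diet alone. Its mean there was 6.14 ± 3.20 (SD) against 8.03 ± 0.59 in controls (exact permutation p = 0.413). The log2 ratio of 3' to 5' control probe sets, a sign of RNA quality, was 2.05 ± 0.47 under the methyl diet and 1.63 ± 0.27 in controls (exact permutation p = 0.103, adjusted 0.619), and 2 of the 11 were called with it as a covariate. Planted changes were called by limma at this stage in 16.4% of cases for a log2 size of 0.5, 68.7% for 1 and 93.9% for 2, with 10 false calls. Here too the shares are likely too high for a few changes, as many were planted at once.

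Among gene groups at 91 dpc, 13 of 14 immediate early genes had negative differences under the methyl diet. None of them passed over all probe sets and 2 were lower adjusted over the list alone, the transcription factors KLF4 (-0.86 ± 0.21) and MYC (-0.57 ± 0.14, a probe set whose ID ends in _s_at). ZFP36 stood at -0.52 and IER5 at -0.41. camera called the list lower (mean -0.37, adjusted p = 0.000229, blocked 0.000316; -0.48 and -0.20 within batches; adjusted p = 0.761 with an estimated correlation). Of 51 oxidative phosphorylation genes 36 had positive differences and 0 passed over all probe sets or adjusted over the list alone, NDUFB5 standing at 0.21 and COX6C at 0.15. camera called the list higher (mean 0.05, adjusted p = 0.000639, blocked 0.000479; adjusted p = 0.761 with an estimated correlation), although its mean was 0.13 within the high-gap batch and -0.05 within the low-gap batch. Complement and acute phase genes had positive differences in 15 of 23 and 0 passed either way, C8A standing at 0.73 ± 0.24 and C1S at 0.42. camera called them higher (mean 0.12, adjusted p = 0.0136, blocked 0.0194; 0.14 and 0.09 within batches; adjusted p = 0.761 with an estimated correlation; 0.0797 without methyl 91 dpc replicate 4 and 0.0510 after quantile normalization). The exact permutation p of the complement mean was 0.0159, adjusted 0.353, and no other list had a smaller one. That test and fry each called 0 of the 34 lists. In the methionine cycle list 12 of 13 genes had negative differences (mean -0.19, camera adjusted p = 0.0855), with CTH at -0.48 ± 0.17. The camera adjusted p was 0.589 for the folate cycle, 0.866 for DNA methylation, 0.568 for histone methylation and 0.71 for imprinted genes. For the hepatocyte secreted and ribosomal protein lists, neither called, the mean was negative (-0.04 and -0.0030) while camera's direction was up. The list count was 9 without control 91 dpc replicate 5 or methyl 91 dpc replicate 2, 6 without methyl 91 dpc replicate 3, and 5 without control 91 dpc replicate 3 or 4 or methyl 91 dpc replicate 1. The mean erythroid level was 9.02 in both diets.

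Named genes just short of the threshold at 91 dpc included PANK1, the first enzyme of coenzyme A synthesis (0.48 ± 0.10, limma adjusted p = 0.0505; -0.29 in a brighter probe set), and the kinase CAMK1D (-0.56 ± 0.12, limma adjusted p = 0.0538, blocked 0.0354). SLC2A1 stood at -1.26 ± 0.29, the mitochondrial gluconeogenic enzyme PCK2 at -0.91 ± 0.22 (-0.92 and -1.29 in its others) and the kinase MKNK1 at -0.71 ± 0.17, each with a limma adjusted p of 0.132. TM9SF4 (-0.92), FBXO32 (-0.91) and KIF3A (1.03, against -0.19 and -0.32 in its other probe sets) did not pass either. In their other probe sets TM9SF4 stood at -0.39 and -0.22 and FBXO32 at -0.48. The controls of PANK1 and KIF3A were near background, as was FBXO32 in some methyl-diet arrays. The size of these uncalled differences is therefore uncertain. IGFBP1 read 13.2 against 13.8 (-0.65 ± 0.26, limma adjusted p = 0.603).

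Averaged over the 3 ages the diet effect had 0 probe sets called by limma, with 685 at an unadjusted p under 0.05 where chance gives 766, a smallest adjusted p of 0.313, 0 with the batch as a block and 1 with block and array weights together. Without control 35 dpc replicate 2, or without control 63 dpc replicate 6, the count was 1. FST (-0.50 ± 0.11), VLDLR (-0.39), VSIG2 (-0.37), HSPA8 (-0.32 ± 0.08) and TMEM87B (0.29) had the smallest p among named genes, with limma adjusted p values from 0.841 up. The test of whether the diet effect differed between ages also had 0 calls by limma, with 660 at an unadjusted p under 0.05 (766 by chance), 0 with the batch as a block and 4 with array weights. SATB1 had diet differences of 0.16, 0.02 and -0.97 at the 3 ages (F = 17.5, limma adjusted p = 0.108), and DDX39B of -0.20, 1.12 and -3.35 (F = 15.7, limma adjusted p = 0.108). CA3 had 0.08, -0.11 and 1.22 (limma adjusted p = 0.410), TAT -0.15, 0.67 and -0.69 (limma adjusted p = 0.410), and MKNK1 had a limma adjusted p of 0.370. No gene was therefore shown to respond to the diet at one age and not at another. The interaction count was 7 without control 35 dpc replicate 4, 2 without methyl 35 dpc replicate 1 or control 91 dpc replicate 5, and 1 without methyl 35 dpc replicate 2, control 91 dpc replicate 1 or 4, or methyl 91 dpc replicate 2.

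A last comparison asked whether the diet moved fetuses along the developmental course, using 200 probe sets per direction of each stage contrast. At 63 dpc the position on the axis from 35 to 63 dpc was 0.54 ± 0.16 under the methyl diet and 0.36 ± 0.57 in controls (SD, n = 6 each), a difference of 0.17 with an exact permutation p of 0.509. The differences were -0.02 at 35 dpc, 0.08 at 63 dpc on the later axis and 0.03 at 91 dpc, and each had an adjusted exact permutation p of 0.937. Averaged within batches the 63 dpc differences were 0.17 and 0.08 and that at 91 dpc was 0.07. Across probe sets, which are not independent replicates, the diet effects of the pairs of ages had r of -0.05, 0.07 and -0.08 with permutation p values of 0.881, 0.515 and 0.683.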

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

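The tests of RNA quality and of the 3 arrays with low EIF1AY, those on DDX39B, and the test for a difference in spread were chosen after the result was seen, and the other tests here before.

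The first pattern is the set of 11 probe sets called for diet at 91 dpc, where methyl-diet arrays had a 3' to 5' ratio of 2.05 against 1.63. With that ratio as a covariate the median of the differences was 0.946 times the original, and the standard errors 1.07 times, so 2 of 11 passed by limma. This cannot decide on RNA quality. The ratio also differed between the spike batches (1.90 in high-gap and 1.40 in low-gap arrays), so 1 slope over all arrays mixes both. Low EIF1AY was found in 3 arrays, among them methyl 91 dpc replicates 4 and 5 and no control at 91 dpc. Without the 3 arrays the median ratio was 0.992 and 0 of 11 passed, because the standard errors grew 1.18-fold. That median ratio argues against those arrays as the whole cause. Diet and RNA quality stay open, and so does fetal sex, which the labels do not give and EIF1AY cannot settle (5 of 11 passed with its level as a covariate).

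The second pattern is DDX39B, lower under the methyl diet at 91 dpc in 1 of its 2 probe sets (-3.35). A change of all DDX39B transcripts is argued against by the brighter probe set, whose difference was 0.00216. The spike batch is argued against by the smaller of the within-batch differences, -2.54. A transcript form or sequence variant matched by this probe set alone may account for it, and the correlation of both probe sets within groups (r = 0.179) leaves this open because neither genome nor probe sequences were used. A diet effect on such a form and a variant shared by litter mates cannot be told apart here.

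The third pattern is the spread of control arrays at 63 dpc on the axis from 35 to 63 dpc, with an SD of 0.573 against 0.155 under the methyl diet. No difference in spread could explain it, as the adjusted exact permutation p was 0.0519. The spike batch is argued against by an SD of 0.6255 about the batch means. A single array is a possible source, since the SD was 0.423 without control 63 dpc replicate 2, but 5 arrays do not settle it. No biological explanation was tested.

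Samples stood apart from their group, relative to its range, in 25 of 364 group tests, where chance flags about 1 in 20 groups (18.2 here). Values are the gap to the nearest sample divided by the group's range. A high value can therefore come from a small log2 gap where the other arrays nearly coincide. TMEM87B in methyl-diet replicate 4 at 35 dpc, for example, read 5.1458 against a mean of 5.1535 in the others. A value of 1 (SATB1, CYP2C91 and SLC2A5) means that the other arrays of the group shared the same value. For CYP2C91 that was the lowest value in the data. In diet genes of methyl-diet arrays at 35 dpc these were VSIG2 in replicate 2 (0.938), TMEM87B in replicate 4 (0.930) and the second CYP4A21;CYP4A24 probe set in replicate 1 (0.864). The mean of ribosomal proteins in replicate 5 of the same group was another (0.723, at 13.9 against 14.1). At 63 dpc they were VSIG2 in control replicate 1 (0.809) and TMEM87B in control replicate 4 (0.856). At 91 dpc the controls had VSIG2 in replicate 4 (0.763), HSPA8 in replicate 3 (0.770) and BCL11A in replicate 5 (0.746). Methyl-diet replicate 1 at 91 dpc stood apart in CA3 (0.748, at 6.93 against 5.82), MKNK1 (0.859), HSPA8 (0.821) and TNNI2 (0.782). In the same group replicate 2 stood apart in SATB1 (1, the other arrays being at the lowest value) and FBXO32 (0.832), and replicate 5 in VSIG2 (0.983). Stage genes at 63 dpc stood apart in control replicate 2 for ALB (0.643) and TRH (0.749), in control replicate 1 for VSNL1 (0.650) and LEAP2 (0.646), and in control replicate 4 for GSTA1 (0.667) and CYP2C91 (1). In methyl-diet replicate 6 at 63 dpc KLKB1 (0.877) and PALMD (0.645) stood apart, and in control replicate 1 at 35 dpc SLC2A5 (1).

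Diet effects on gene lists differed between ages by camera on the difference itself, values being adjusted p. From 35 to 63 dpc the effect moved up for urea cycle and amino acid breakdown (0.00315), ribosomal proteins (0.00315), fatty acid oxidation (0.0339) and hypoxia, heat shock and unfolded protein response (0.0339), and down for muscle (0.00315). From 63 to 91 dpc it moved down for the methionine cycle (0.00252), urea cycle (0.0295), immediate early genes (0.000221) and lymphocytes (0.0112). Over the same ages it moved up for cell cycle (0.00252), complement (0.00252), oxidative phosphorylation (0.00252) and muscle (0.00899). Between 35 and 91 dpc it moved down for the methionine cycle (0.0376), immediate early genes (0.000626) and lymphocytes (0.0466), and up for oxidative phosphorylation (0.000444) and ribosomal proteins (0.00171). None held with an estimated correlation, and fry called 1, the methionine cycle between 63 and 91 dpc. All were kept with the batch as a block (5, 8 and 5).

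Regrouping the arrays (100 splits of each result, the real one included) shows where chance can be excluded. It is excluded for the stage counts of 9278 (1 split as large, highest other 1375) and 8963 (1, highest other 4406). For the 8 lists whose diet effect differed between 63 and 91 dpc, 2 splits were as large and the highest other gave 9. That share is under 0.05 for this result alone, was not adjusted for the other results compared this way, and 0 of these lists held with an estimated correlation. Chance is not excluded for the diet counts of 6 at 35 dpc (37, highest other 978) and 11 at 91 dpc (27, highest other 489). A real count of 0 makes all 100 splits as large, so the comparison says nothing about chance for diet at 63 dpc (highest other 896), the averaged effect (highest other 817) and the interaction (highest other 169). Among list counts it is not excluded for diet at 35 dpc (2; 61, highest other 7), 63 dpc (3; 6, highest other 5) and 91 dpc (3; 69, highest other 9), nor for stage (8; 15, highest other 14, and 14; 10, highest other 17). The same holds for the list differences 63 minus 35 dpc (5; 6, highest other 6) and 91 minus 35 dpc (5; 24, highest other 12). Some regroupings thus called 978, 896 or 489 probe sets. What the arrays grouped by them share was not tested, apart from the spike batch at 63 dpc. Splitting the 63 dpc arrays by spike batch called 167 probe sets and 0 lists, with 0 for diet in the blocked fit.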

How the results depend on the processing

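The spike batch settings, the block with array weights, and the fit without the 3 arrays with low EIF1AY were chosen after the data were seen. Both stage counts kept within 1.5 times under robust spread, no trend, either filter, quantile normalization, array weights, the EIF1AY and 3' to 5' covariates, and the batch block. Of 137 called stage results for named genes, 137 were kept in direction and call with the block, 137 with quantile normalization and 81 with the erythroid covariate, where 47 lost the call and 9 reversed. The erythroid mean changes with age, so that setting removes much of what separates the stages. Of 6 called diet results for named genes, the block kept 6, quantile normalization 5, the 3' to 5' covariate 3, the high-gap batch 2, the low-gap batch 1, and the arrays of 1 stage 0. The last has fewer arrays for the spread. It also leaves out ages at which some called probe sets lay near background and varied little. For CA3 the SD was 0.12 at 63 dpc, against 0.67 and 0.51 in the control and methyl-diet groups at 91 dpc. The main fit pools the spread over all ages, so its standard errors may be too small for such probe sets. Signal near the lowest value limits the diet calls: the higher group mean lay under 4 in 5 of the 6 at 35 dpc and in 2 of the 11 at 91 dpc. For settings where nothing is said of the cause, the cause was not tested. Not run were log2(value + 16), as the values were already log2, and the fit of 1 stage alone for the averaged effect and the interaction, which need all ages. XIST has no named probe set, so EIF1AY stood in. Some genes gave no value under the stricter filter or with 1 probe set per gene.

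Diet counts at 35 dpc (6) were 18 with no filter, 0 with the stricter filter and 0 with 1 probe set per gene (fewer probe sets tested). The stricter filter still tested 1 of the 6 called probe sets, and 1 probe set per gene tested 0 of them. The count was 3 with the EIF1AY covariate, and 13 in the high-gap and 0 in the low-gap batch (fewer arrays). It was 13 at a threshold of 0.10 and 0 with the arrays of that stage alone. At 63 dpc (0) the count was 4 with block and array weights. At 91 dpc (11) it was 2 with the stricter filter, 37 with array weights and 0 with 1 probe set per gene. The stricter filter still tested 4 of the 11 called probe sets and kept 2, and 1 probe set per gene tested 1 of the 11. The count was 5 with the EIF1AY covariate, 2 with the 3' to 5' covariate, and 41 in the high-gap and 4 in the low-gap batch. It was 42 with block and array weights, 1 without the 3 arrays with low EIF1AY and 0 with that stage alone. The averaged effect (0) had 1 with block and array weights. The interaction (0) had 4 with array weights, 6 in the high-gap and 2 in the low-gap batch, and 4 with block and array weights. Stage counts were 3934 and 3545 with 1 probe set per gene, 4798 and 5260 in the low-gap batch, and for the later interval 808 with the erythroid covariate.

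List counts were 0 with an estimated correlation for diet at 35, 63 and 91 dpc and for both stage effects. fry gave 0, 0 and 0 for diet, and 26 and 27 for stage. For diet at 35 dpc (2) the mean of all probe sets of a gene gave 0, quantile normalization 1 and the low-gap batch 0. At 63 dpc (3) the high-gap batch gave 1 and the low-gap batch 9. At 91 dpc (3) the erythroid covariate gave 5 and the low-gap batch 0. For the later stage effect (14) the erythroid covariate gave 7.

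Some named genes reversed. With 1 probe set per gene, a brighter probe set replaced the one named (called for DDX39B, not called for KIF3A and PANK1), and the differences at 91 dpc were 0.0022 for DDX39B, -0.32 for KIF3A and -0.29 for PANK1. The change of AFP from 63 to 91 dpc was 0.036 with quantile normalization, 0.018 with the 3' to 5' covariate and 0.16 with the erythroid covariate. The change of IGF2 from 35 to 63 dpc was 0.017 with array weights and 0.058 in the high-gap batch, where MAT1A changed by 0.016 and GNMT, in the later interval, by 0.076. BHMT in the later interval changed by 0.27 with the 3' to 5' covariate and by 0.26 in the low-gap batch. RPS24 at 35 dpc differed by 0.021 in the low-gap batch. With the erythroid covariate the later-interval changes were -0.24 for ABCG8, -0.61 for APCS, -0.51 for CYP39A1, 0.64 for DNMT3B, 0.88 for GNMT, -0.96 for GSTA1, -0.31 for GSTA4, -0.053 for IGF2, -0.052 for IGFBP1, 0.013 for LTF and 0.034 for PRDX2. The developmental position difference at 35 dpc was 0.10 with 50 probe sets on each side.

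Leaving out each array in turn gave diet counts of 4 to 13 at 35 dpc, 1 to 43 at 91 dpc, 0 to 1 for the averaged effect and 0 to 7 for the interaction. List counts for diet ran from 1 to 3 at 35 dpc, 1 to 7 at 63 dpc and 2 to 9 at 91 dpc. The later-interval change ran from -0.22 to 0.023 for BHMT and from -0.15 to 0.0063 for GNMT. Position differences ran from -0.21 to 0.18 at 35 dpc, from -0.029 to 0.32 and from -0.069 to 0.30 at 63 dpc on the earlier and later axis, and from -0.15 to 0.19 at 91 dpc. Of 192 left-out results for the 6 called diet genes, 143 kept the call, as did 4367 of 4384 for stage genes.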

Other observations

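The observations of stage courses in this part were made after the data were seen. Of 6383 probe sets that limma called in both stage intervals, 3185 rose in both and 2919 fell in both, while 227 rose and then fell and 52 fell and then rose. Named genes that rose to 63 dpc and fell to 91 dpc, with no test of the group they form, included the antimicrobial peptides NPG4 (1.80, then a fall, in the probe set with the largest change) and PR39 (1.27, then -1.22), PGLYRP1 (1.47, then -1.31), LTF (1.15, then -0.99), and the calgranulins S100A12 (0.99, then -1.42) and S100A8 (0.92, then -1.69). The fructose transporter SLC2A5 followed the same course (2.85, then -2.04). Those that fell and then rose included the matrix proteoglycan DCN (-0.87, then 1.29), FKBP10, a prolyl isomerase of collagen folding (-0.85, then 0.91), the biliary keratin KRT19 (-0.89, then 0.71), and the complement gene C8B (-0.77, then 2.13, in another probe set than the one in the complement list). TCN2, which carries vitamin B12, fell by 0.67 and rose by 0.60. CA3, higher under the methyl diet at 91 dpc, fell by 0.91 and rose by 2.81 in its other probe set.

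Averaged over the 3 ages, camera called 2 lists for diet. Neutrophil and granulocyte genes were higher, with positive differences in 9 of 10 (mean 0.18; 0.29 and 0.05 within batches; adjusted p = 0.00133, blocked 0.00222; adjusted p = 0.754 with an estimated correlation). Hypoxia, heat shock and unfolded protein response genes were lower, with negative differences in 19 of 24 (mean -0.10; -0.13 and -0.06 within batches; adjusted p = 0.00472, blocked 0.00840; adjusted p = 0.754 with an estimated correlation). Of these, 0 passed over all probe sets and 2 were lower adjusted over the list alone. In the folate list 3 genes rose and 10 fell among 18 from 63 to 91 dpc (camera adjusted p = 0.457), and PSPH fell by 1.32, PHGDH by 1.12 and TYMS, thymidylate synthase, by 1.46. The imprinted genes PEG10 and TFPI2 each rose by 1.98 from 35 to 63 dpc and NNAT fell by 1.36, while 6 rises and 4 falls among 16 imprinted genes gave a camera adjusted p of 0.458.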
